A study of Mus musculus with 6 samples.

How the data were processed

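RNA was sequenced from 6 mouse samples of the C57BL/6 strain, 3 labelled as wild-type controls and 3 labelled MIRI (myocardial ischemia-reperfusion injury, in which blood flow to the heart muscle is blocked and then restored). The labels gave total RNA and a TruSeq RNA library kit. They gave conflicting tissues: the tissue field named retina, the extraction protocol named the intervertebral disc, and the condition named the heart muscle. No tissue was therefore assumed. The groups follow the sample labels, but the names of the deposited files call the control samples WT and the MIRI samples mutant, and the genotype field of the latter holds the injury. Whether a mutant was involved is not known, so a difference between the groups may stem from a genotype, from the injury or from both. It may also stem from sex, batch, the mix of cells or anything else that differs between them. The series' design text named 21-day-old mice. Sex, time after injury and batch were not given in the sources used here, and nothing stated that the 3 samples of a group were separate animals, so p-values measure the spread between these samples, which may be technical.

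The authors deposited whole-number counts of read pairs per gene name for each sample and a table of the series that holds the same counts beside FPKM values. Per the file headers, the counts were made with featureCounts 2.0.1 on exons grouped by gene name, with both mates required to align, chimeric pairs left out and no strand setting, so that reads of a gene and of its antisense partner were not told apart. The submitters' processing notes listed Bowtie 0.12.2 and the builds mm8 and mm9, while the series' design text named BWA, TopHat and Cufflinks. Which aligner and build made these alignments, and the build of the annotation used in counting, were not given in the sources used here. The alignment files named in the headers carry public archive run names, not sample names, so each count column was assigned through the sample that its file belongs to.

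The table held 53509 rows, and each of the 6 sample files was equal to it in all of them. The sample files held 37 further rows of the mitochondrial chromosome, with 0 counts in each library. Total counts ran from 6859481 to 9250952 per sample, so that 1 count was 0.108 to 0.146 CPM. The deposited FPKM values were the counts divided by row length and then by a constant equal to the squared total count of the sample, a ratio of 1.0 in every library. They were thus divided by library size 2 times over, and the deepest library had the lowest FPKM sum (38423, against 48096 to 52237 in the others). The counts were used for the main tests, and FPKM values only as an alternative. No 2 libraries were alike within sampling noise (chi-square per degree of freedom of 4.75 or more for each pair). Every column was mapped to a sample.

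The position of the rows was examined because genes transcribed in most cells had almost no counts. The exon intervals of each row, as the files give them, were laid over the exons of GENCODE M21 on the GRCm38 assembly with bedtools 2.31.1, without converting any coordinate. As a check, the intervals were also moved by 20 to 500 kb in both directions. A row was called in place when at least 95% of its length lay on exons of the gene it is named for. After the data were seen, a second set of names was made: a row was assigned to the GRCm38 gene that held at least 80% of the exon bases it overlapped and at least 50 bp, and counts were summed per gene. This named 14930 rows, with 61.4% of all counts, for 11910 genes. All counts of a row went to its gene, also those from bases of the row outside that gene's exons. Such a gene is thus covered over part of its exons and may hold reads from elsewhere. Levels of different genes cannot be compared, while the same gene, as the same set of rows, can be compared between libraries.

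Groups were compared with edgeR 4.0.16 (TMM scaling, filterByExpr at its default, glmQLFit and glmQLFTest, group as the only term) in R 4.3.3. The tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design, the alternatives and 40 gene lists were fixed before the data were examined. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2. The same lists were tested with an estimated correlation and with fry, which tests a list alone and does not compare it with other genes. Shares of tissue marker genes were compared with exact permutation tests, for which 3 against 3 samples give no p below 0.1. CPM in the text are relative to all counts of the library. Values on the log2 CPM scale are instead relative to the TMM-scaled counts of the tested genes alone, so the 2 scales cannot be compared.

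The genes to name were also fixed before: among genes with a mean of at least 2 CPM, groups that do not overlap and a symbol that is not provisional, the 10 per direction with the largest fold change of those past the threshold or, if none passed, the 5 per direction with the smallest p. The 4 members with the smallest p of a called list, up to 2 of other biological lists, up to 3 most abundant members of a tissue marker list, and a fixed set with Nppa, Nppb, Myh6, Myh7, Acan and Col2a1 were added. Some genes named by this rule are not reported here. The same rule was applied to names by position.

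Alternatives were DESeq2 1.42.0 size factors and its Wald test, upper-quartile factors, limma-voom, no low-count filter and a stricter one, FPKM with pseudocounts of 1 and 0.1, a minimum fold of 1.5, rows with an official symbol only, a replicate block and leaving out each library. Added after the data were seen were the names by position, 5 variants of that rule, and FPKM divided by library size once. The edgeR test and camera at the preset correlation were tested on simulated counts. These were drawn from the real means, library sizes and spread of each gene as edgeR estimates it. The naming by position was tried on a few made-up intervals, and the other tests were not simulated. For MIRI against control with the deposited names (15421 genes), 56.7% of 2-fold, 98.5% of 4-fold and 100% of 16-fold changes were recovered, and 9.6% of calls were unchanged genes. With names by position (5855 genes), 74.6%, 98.5% and 100% were recovered and 6.7% of calls were unchanged genes. Changes were planted only in genes with a mean above 5 CPM, and each gene was drawn independently. The recovered shares therefore do not hold for genes at lower levels. A lack of calls does not exclude large changes with a wide spread between libraries. Pecam1 by position, for example, had a log2 fold change of -4.74 and an edgeR adjusted p of 0.187.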

Results

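Gene expression was measured by RNA sequencing in 3 control and 3 MIRI mouse libraries. The libraries held 7383278, 7303796 and 9250952 counts in controls 1 to 3, and 7432917, 6859481 and 7383546 in MIRI 1 to 3. The design asks which genes and gene groups differ after myocardial ischemia-reperfusion injury. The labels disagree on the tissue, so values are given without a tissue name, and the file names call the MIRI samples mutant, so the groups may differ in more than the injury.

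The names and the counts of the deposited rows did not go together. Rows named for Col1a1, Sparc, Tmsb4x, Rpl3 and Eef1a1, which encode collagen, matrix, actin-binding and translation proteins, had mean levels of 0.018, 0.193, 0, 0.047 and 0.047 CPM. The row named Itga3 (chromosome 11, 94935300 to 94967627 in the coordinates of the files) had 8798 CPM, and on GRCm38 its intervals lie on exons of Col1a1. The row Atic (chromosome 1, 71596309 to 71618790) lies on exons of Fn1 and had 18453 CPM, the row G3bp1 lies on Sparc (10964 CPM), and the row Ltbp3 lies on the long noncoding RNA Malat1 (60569 CPM). These examples were chosen after the values were seen.

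Rows that overlap a GRCm38 exon made up 36.8% of rows and held 95.1% of counts. When the intervals were moved by 20 to 500 kb, the share of counts was between 59.7% and 80%. Of 50030 row names that GENCODE M21 also holds, 2.72% had the same start and end there, and 98.0% had the same span. The median offset of the starts ran from -956.4 kb on the X chromosome to 490.0 kb on chromosome 8, and was 0 on the Y chromosome. Rows in place made up 3.1% of rows and 8.5% of counts, among them Col1a2, a collagen I chain (13405 CPM), and the ribosomal protein gene Rps20 (1060 CPM). Rows lying on another single gene held 43.5% of counts, rows over several genes, or over less than 50 bp of exon, 33.6%, and rows shifted along their own gene 9.4%.

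**Figure D1:**
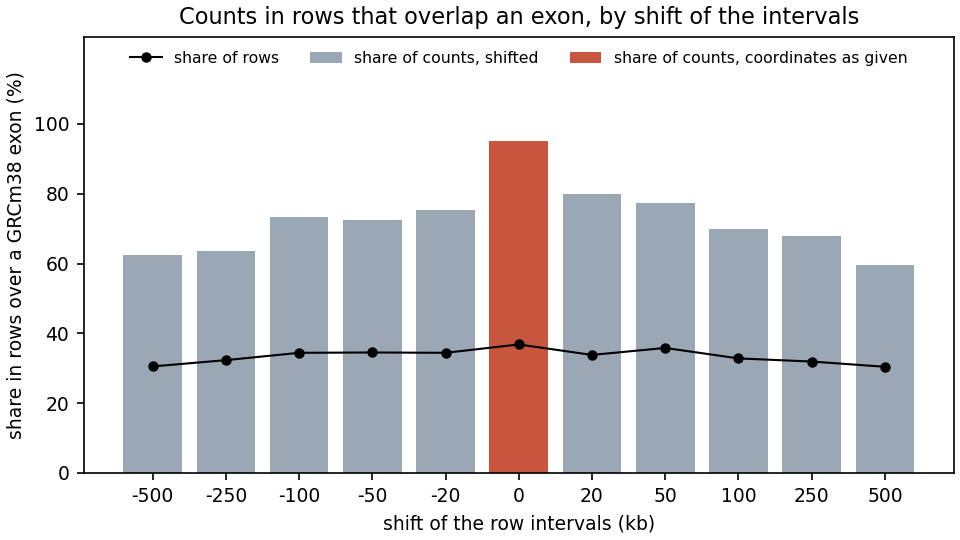
Share of all counts (bars) and of rows (line) in rows that overlap a GRCm38 exon, in percent, for row intervals as given and moved by up to 500 kb. With the coordinates as given the share of counts was 95.1%, and no shift gave more than 80%.

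Among rows named for housekeeping families, 8 were in place, with a median of 59.7 CPM, and 6 of them were above 20 CPM. The 355 not in place had a median of 1.27 CPM, and 69 of them (19.4%) were above 20 CPM (Fisher's exact test, two-sided, p = 1.3e-03). These families were ribosomal protein, proteasome, respiratory chain, translation factor, chaperonin, COP9, splicing and RNA polymerase II genes. Rows with other names that lie on such genes had a median of 27.7 CPM.

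With the deposited names, no gene of MIRI differed from control past the threshold. Among 15777 rows tested with edgeR, 0 were called higher and 0 lower, and the smallest adjusted p was 0.105. An unadjusted p under 0.05 was found for 685 rows (256 higher, 429 lower). This was 4.3% of rows, where chance alone gives a share of 0.05. The groups did not overlap in 1390 rows (8.8%), where chance gives 10%. The DESeq2 test called 6 higher and 80 lower. Without control 1, edgeR called 31 lower, and without a low-count filter 124 higher and 231 lower.

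The 5 rows with the smallest p in the lower direction did not pass. They were Cd46, Blzf1, Ptgfr, Ifi44 and Cr1l, with log2 fold changes of -0.91 ± 0.10 (SE), -2.18 ± 0.27, -3.42 ± 0.45, -3.64 ± 0.49 and -0.85 ± 0.12 and edgeR adjusted p of 0.105 for the first 4 and 0.11 for Cr1l. At the file coordinates none of these rows lies on the gene it is named for. Blzf1 (chromosome 1, 164117369 to 164135058) lies on exons of Selp, Ptgfr and Ifi44 on exons of Adgrl4, and Cr1l on exons of Plxna2, while Cd46 overlaps 47 bp of exon. In the higher direction the rows were Uty, Kdm5d, Eif2s3y and Ddx3y, all on the Y chromosome and in place, and Rhoh (1.55 ± 0.34, adjusted p = 0.303), which lies on Rbm47. The row named Selp had a log2 fold change of 0.29 ± 0.17, against -2.18 ± 0.28 for the gene Selp by position.

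Of 35 gene lists tested with the deposited names, camera called 0 (smallest adjusted p 0.453), and the list medians lay between -0.09 and 0.15. The list with the smallest p was the endothelial markers: 7 of 9 tested rows were lower, 0 passed over all rows and 2, Vwf and Flt1, passed when adjusted over the list alone. The row Vwf, which is shifted along its own gene, that of the clotting protein von Willebrand factor, had -3.69 ± 0.69. The row Flt1 had -0.39 ± 0.12, but no single gene holds 80% of the exon bases it overlaps, so this cannot be read as a value of that gene. By fry and by camera with an estimated correlation no list passed either.

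Named by position, endothelial genes were lower in MIRI as a group. These are genes of the cells that line blood vessels. Pecam1, an adhesion molecule of endothelial junctions, was at 224 ± 141 CPM (SD, n = 3) in controls and 8.4 ± 9.36 in MIRI. Tie1, an endothelial receptor kinase, was at 72.4 ± 48 and 2.29 ± 3.08 CPM, and Vwf at 35.7 ± 22.4 and 2.72 ± 2.44. All 7 measured members of the 20 listed were lower, 6 of them with groups that did not overlap. The median log2 fold change was -4.74, and -6.14 without MIRI 1, which had the highest Pecam1, Tie1 and Vwf levels of its group (19.1, 5.79 and 5.52 CPM). The list fell by camera with an adjusted p of 6.48e-16 over 22 lists, and by fry with an adjusted p of 0.0429. With an estimated correlation the call was lost (adjusted p = 0.176).

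**Figure D2:**
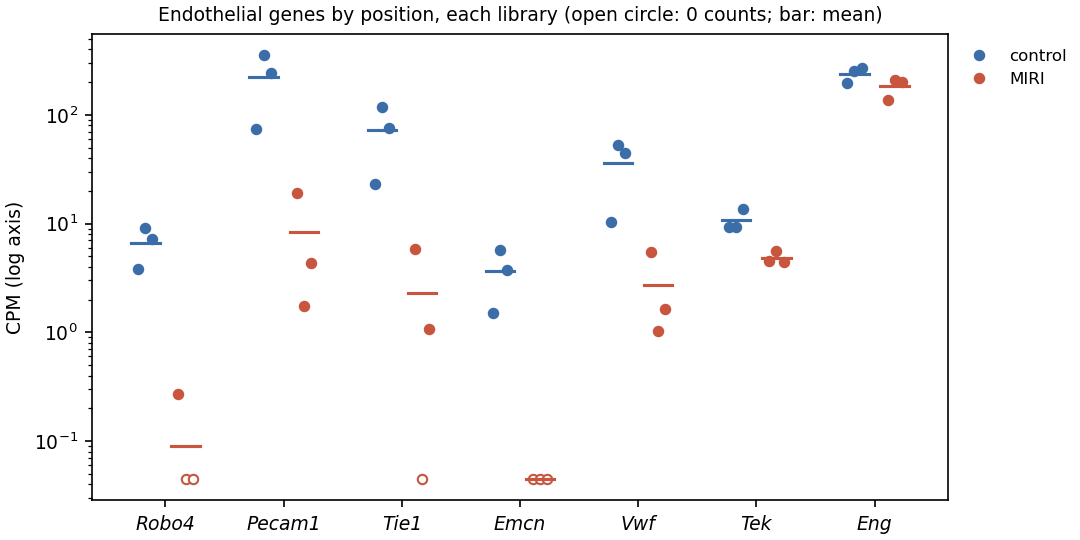
CPM of the 7 endothelial genes measured by position, on a log axis, with 1 point per library, a bar at the group mean, and open circles for libraries with 0 counts. The MIRI libraries lie below all controls in 6 genes, while Eng overlaps.

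No single gene passed by position. Of 5917 genes tested with edgeR, 0 were called higher and 0 lower. An unadjusted p under 0.05 was found for 272 (97 higher, 175 lower), which was 4.6%, where chance alone gives a share of 0.05. The groups did not overlap in 529 (8.9%, where chance gives 10%). The smallest adjusted p was 0.082, and 23 of the 24 genes under 0.25 were lower. The DESeq2 test called 9 higher and 46 lower. Without a low-count filter edgeR called 4 and 28, and 14 were called lower without control 1, 2 without control 2 and 1 without control 3. Adjusted over the list alone, 6 endothelial genes were lower: Robo4, Pecam1, Tie1, Emcn, Vwf and Tek. Control 1 had the lowest mean level of the 7 genes among controls (4.69 on the log2 CPM scale, against 6.12 and 5.94). MIRI libraries were at 2.94, 1.56 and 2.09 (difference of means -3.38, exact permutation p = 0.1, the smallest possible).

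Pecam1 (GRCm38 chromosome 11, 106654217 to 106750628) was covered by 4 rows named Cep95, Ddx5, Milr1 and Polg2, which overlap 2027 bp of its exons. Their levels in control and MIRI libraries were 108 ± 68.8 and 3.56 ± 4.42 CPM for Cep95, 56 ± 34.9 and 2.13 ± 2.14 for Ddx5, 44.3 ± 26.3 and 1.67 ± 1.85 for Milr1, and 15.7 ± 11.4 and 1.04 ± 0.962 for Polg2. The row named Pecam1 overlaps no GRCm38 exon and had 7.75 ± 3.11 and 7.91 ± 1.32 CPM. The fitted log2 fold change of the gene was -4.74 ± 0.83 (edgeR adjusted p = 0.187).

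**Figure D3:**
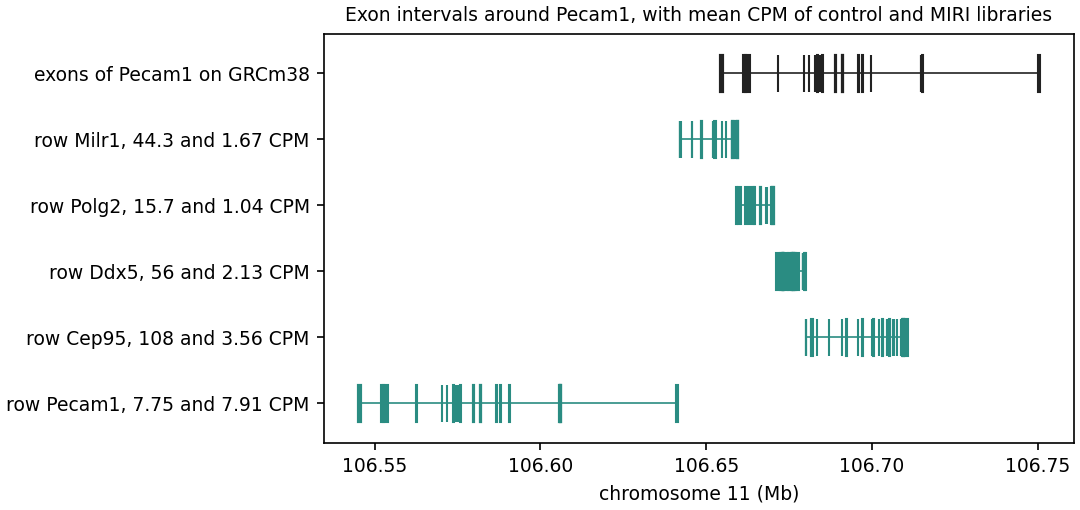
Exons of Pecam1 on GRCm38 (black) and exon intervals of 5 rows at the coordinates of the files (green), along chromosome 11 in Mb, with mean CPM of control and MIRI libraries. The rows that lie on Pecam1 exons have 108, 56, 44.3 and 15.7 CPM in controls and 3.56, 2.13, 1.67 and 1.04 in MIRI, while the row named Pecam1 lies elsewhere and has 7.75 and 7.91.

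Robo4, a guidance receptor of endothelial cells (chromosome 9, 37401897 to 37415115), had 161 summed counts in controls and 2 in MIRI, a 72.9-fold difference with an exact 95% interval of 19.9 to 607 that covers counting error only. Both MIRI counts came from MIRI 1, and the other 2 MIRI libraries had 0, so without it the data give only a lower bound on the fold. Its log2 fold change was -5.95 ± 0.74 (edgeR adjusted p = 0.082). Emcn, which encodes the surface protein endomucin, had 88 counts in controls and 0 in MIRI. It was at least 26.6-fold lower in summed counts, taking 3 counts over the group as the floor. This bound covers counting error only, and the controls had 11, 42 and 35 counts, from 1 row covering 107 bp. The list median with this bound was -4.73. Tek, another endothelial receptor kinase, differed less (-1.15 ± 0.25, adjusted p = 0.286), and Eng was at -0.38 ± 0.20.

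Genes outside the list with the smallest p included Adgrl4, an adhesion receptor of endothelial cells (-3.43 ± 0.38, 29.1 ± 13.1 and 2.71 ± 0.803 CPM, edgeR adjusted p = 0.082). Selp, which encodes the adhesion molecule P-selectin of platelets and endothelium, was at 128 ± 54.7 and 28.2 ± 3.64 CPM. Plxna2, a semaphorin receptor, had -0.86 ± 0.11, and Fam167b -3.83 ± 0.53 with an adjusted p of 0.113. In the higher direction Adamts14, a procollagen protease, had 1.18 ± 0.24 (adjusted p = 0.262) from a single row covering 75 bp.

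The angiogenesis and growth factor list was also called lower by camera (adjusted p = 0.0445, 6 members, median -0.34), and its members went both ways. The call was lost with an estimated correlation (adjusted p = 0.456) and with fry (0.258). Pdgfb (-3.20 ± 0.52), Pgf (-2.04 ± 0.45) and Angpt2 (-0.77 ± 0.24), all growth factors acting on vessels, passed when adjusted over the list alone, and none passed over all genes. Hgf was at 1.34 ± 0.63, with 35 ± 11.3 CPM in controls and 183, 22.6 and 62.6 CPM in MIRI 1 to 3, and without MIRI 1 its log2 fold change was 0.33.

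Genes of glycolysis and the hypoxia response were called higher by camera (adjusted p = 0.0297), with 14 of 15 members higher, 0 past the threshold over all genes or over the list alone, and a median log2 fold change of 0.17. The call was lost with an estimated correlation (adjusted p = 0.666) and with fry (0.586). The 4 members with the smallest p were Pfkl (0.17 ± 0.11), Pfkm (0.15 ± 0.10), Eno1 (0.33 ± 0.22) and Pdk1 (0.23 ± 0.16), which encode glycolytic enzymes and a kinase of pyruvate dehydrogenase.

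The other 19 lists by position were not called, with medians from -0.21 to 0.21. The coagulation list came nearest (adjusted p = 0.0546), in the lower direction by camera although the median of its 7 members was 0.12. Selp and Vwf had its smallest p, and 3 members passed when adjusted over the list alone, all lower. Immediate early genes, which respond within minutes to stimuli, had a median of -0.21 (adjusted p = 0.0673), with Dusp1 at -0.40 ± 0.15 and Fos at -0.50 ± 0.29. Circadian clock genes had a median of -0.19 (adjusted p = 0.0911), with Nr1d2 at -0.30 ± 0.11. Fibroblast and matrix genes had a median of 0.08 over 16 members (adjusted p = 0.615). Among them Dcn, a collagen-binding proteoglycan, was at -0.62 ± 0.23 and Thbs2 at 0.68 ± 0.27. Lists of mitochondrial fatty acid oxidation, citrate cycle, unfolded protein response, heat shock and interferon genes had adjusted p of 0.615, 0.807, 0.807, 0.807 and 0.807.

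Marker shares of tissues are given as values, since an exact permutation test of 3 against 3 samples has no p below 0.1 and could not have passed (smallest p 0.2 with either naming). Rows named for sarcomere genes took 0.187 ± 0.0124% of counts in controls and 0.187 ± 0.0168% in MIRI, led by Mb, Tnnt2 and Ttn. Rows named for photoreceptor genes took 0.0309 ± 0.00238% and 0.0299 ± 0.00148%. Most rows do not lie on the gene they are named for, so these are shares of names. The row named Ttn had 423 CPM, and Ttn by position had 0.462 CPM. Named by position, the 7 sarcomere genes present, of 24 listed, took 0.000761 ± 0.000239% and 0.000672 ± 0.000341%, led by Myom1 at 5.3 CPM. They are measured over part of their exons, so neither share tells how much muscle RNA the libraries held. The 10 disc and cartilage genes took 0.00821 ± 0.000864% and 0.00802 ± 0.00104%, and the 8 photoreceptor genes 0.0027 ± 0.000617% and 0.0035 ± 0.000464%. Bone markers took 0.789 ± 0.121% and 0.972 ± 0.13%, nearly all from Col1a1.

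Rows named for the heart stress hormones Nppa and Nppb had 2 to 7 and 1 to 6 counts per library, and rows named Myh6 and Myh7, the cardiac myosin heavy chains, at most 2 and 1. None of these 4 was tested. By position Myh6 had 0 counts in each library, which allows up to 0.324 CPM in the deepest one, over the part of its exons that rows cover. Nppa, Nppb, Myh7 and Col2a1 had no row named by position. The row Col2a1 lies on Vdr and had a log2 fold change of 0.49 ± 0.42. The row Acan had 0 to 4 counts, and Acan by position 6, 12 and 3 counts in controls and 0 in each MIRI library.

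The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y lie in place, and their counts are the same by row and by position. They had 1.49 ± 1.1, 1.04 ± 0.608, 0.794 ± 0.595 and 1.05 ± 0.571 CPM in controls and 43.1 ± 48.8, 33.8 ± 39.4, 30 ± 34.9 and 26.3 ± 30.9 CPM in MIRI. The MIRI libraries differed widely: Ddx3y, a Y-linked RNA helicase, was at 98.6, 6.71 and 24.1 CPM in MIRI 1 to 3. No adjusted p passed in the main edgeR test (0.262 to 0.282 by position). All 4 were called higher by the DESeq2 test and, by position, by edgeR without a low-count filter. The endothelial genes above were lower in the same libraries as a group. Within MIRI the order was not opposite: MIRI 1 had the highest and MIRI 2 the lowest level of both. The endothelial means were 2.94, 1.56 and 2.09 in MIRI 1 to 3 on the log2 CPM scale.

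**Figure D4:**
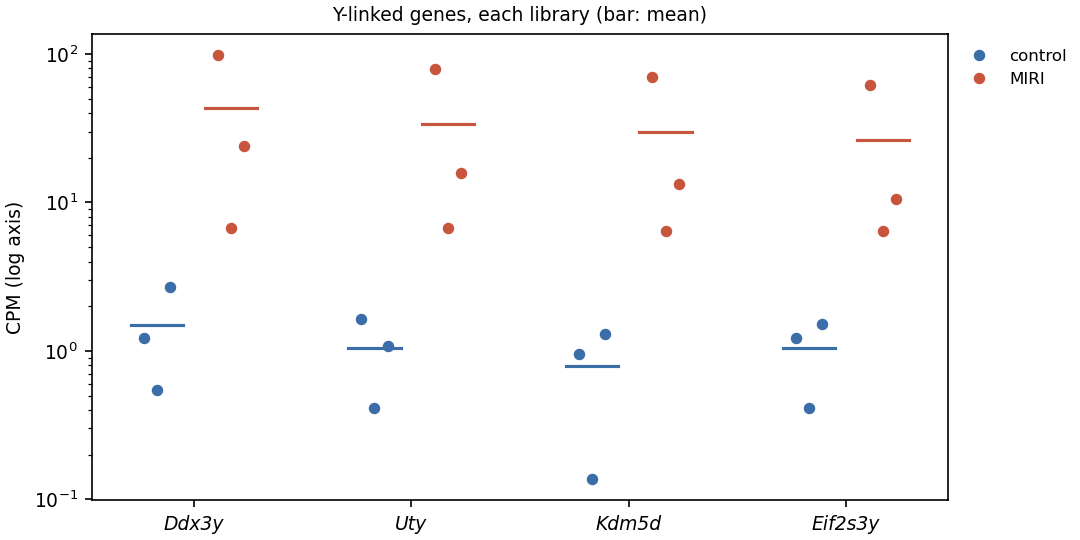
CPM of 4 Y-linked genes in each library, on a log axis, with a bar at the group mean. Each MIRI library lies above each control library in all 4 genes, and MIRI 1 has the highest level.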

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

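Among the alternatives reported here, all those on names by position and the FPKM values divided by library size once were chosen after the data were seen. The others were planned.

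With the deposited names the 0 calls stayed at 0 with DESeq2 size factors, upper-quartile factors, limma-voom, a stricter filter, a minimum fold of 1.5 and official symbols only. The DESeq2 test called 6 higher and 80 lower, and no low-count filter 124 and 231. All 80 of the former were among the latter. Both FPKM fits called 2 lower, and FPKM divided by library size once called 1 higher. The median log2 fold change over the 6538 rows tested in deposited FPKM was 0.13 with a pseudocount of 0.1 and 0.09 with 1. Leaving out 1 library gave 0 higher and 0 to 31 lower, the 31 without control 1. No list was called in any setting. Shares of tissue markers in FPKM were 0.026% for photoreceptor, 0.00956% other retinal, 0.0756% disc and cartilage, 0.158% sarcomere, 0.0157% skeletal muscle, 0.0202% adipocyte, 0.0203% neuron and Schwann cell, 0.00949% hepatocyte, 0.0243% bone, 0.0115% kidney and lung, and 0.00778% erythroid genes. The total without mitochondrial genes was the same, since the table has none.

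By position, the DESeq2 test called 9 higher and 46 lower, and no low-count filter 4 and 28, of which 27 were among the 46. Leaving out 1 library gave 0 higher and 0 to 14 lower. The 4 other rules for naming rows and rows in place only called 0. The list count of 1 higher became 0 with an estimated correlation, fry, no filter and 200 bp of overlap, and ranged from 0 to 2 without 1 library. The 2 lower lists became 0, 1 and 1 with an estimated correlation, fry and no filter, and ranged from 1 to 3 without 1 library. For the endothelial list the adjusted p was 0.176 with an estimated correlation, and under 0.05 elsewhere, and its median ranged from -6.14 to -4.27 without 1 library. For glycolysis it was 0.076 without a filter, 0.666 with an estimated correlation, 0.586 with fry, 0.0734 at 200 bp, and 0.00615 to 0.298 without 1 library. For angiogenesis it was 0.076 without a filter, 0.456 with an estimated correlation, 0.258 with fry, and 0.0167 to 0.149 without 1 library. The causes were not tested.

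A replicate block gave 0 calls in both directions with either naming and no list by deposited names. By position it called 1 list higher and 2 lower. Same-numbered samples did not deviate together (correlations of -0.15, -0.27 and 0.15 with the deposited names), and no control correlated best with its own number, so the numbers were not taken to pair the samples. Of 49 named genes, 27 passed with the DESeq2 test. Leaving out 1 library, the log2 fold changes ranged from -0.06 to 0.73 for Cenpf and from -0.19 to 0.67 for Kif11, both turning below 0 without MIRI 1. Depth limits rows under about 1 CPM, since 1 count was 0.108 to 0.146 CPM.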

Other observations

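The test on a second endothelial list and the splits with the deposited names were written before their results were seen, and all other tests here were chosen after.

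Control 2 and MIRI 1 differed from the other libraries in a direction that crosses the groups. On the first principal component (33.9% of the variance) control 2 lay at 37.3 and MIRI 1 at 33.9, and the others between -29.4 and -7.2. The second component (26.3%) had controls at -8.9, -24 and -30.7 and MIRI at 32.5, 16.6 and 14.5. Cell cycle genes named by position, among them Cenpf and Kif11, which encode a centromere protein and a spindle motor, had the highest mean levels in the same libraries. On the log2 CPM scale the means were 6.16, 6.95 and 5.75 in controls 1 to 3 and 7.13, 6.10 and 6.30 in MIRI 1 to 3.

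The share of counts in rows over a GRCm38 exon was 95.1% at the coordinates given and at most 80% at the 10 shifts. This fits intervals that were counted on another genome build than the alignments. Low expression of the housekeeping genes themselves predicted no difference between rows in place and others, but these differed (Fisher's exact test, p = 1.3e-03). The 2 explanations do not depend on the groups, and no biological explanation was tested. A new count from the alignments with a matching annotation would decide it.

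Endothelial genes by position differed by a median log2 fold change of -4.74. A scaling error would shift all genes alike. The median of all genes stayed within 0.02 of 0 under each scaling, but each scaling centres the genes, so this is no test. A common shift would leave the distance between this list and others unchanged. The highest median of the list over the scalings was -4.73, and the lists not called by position had medians from -0.21 to 0.21. Scaling does not account for that distance. A lower share of endothelial cells in the MIRI libraries predicted a median of -1 or below in a second list of other endothelial genes, and above -0.5 otherwise. Of 41 genes written for this list, 7 were measured. They were Ednrb (-2.46 ± 0.71), Ptprb (-0.96 ± 0.35), Calcrl (-0.73 ± 0.62), Notch4 (-0.53 ± 0.16), Ephb4 (-0.28 ± 0.11), Tspan12 (-0.15 ± 0.28) and Tmem204 (-0.15 ± 0.27). All 7 were lower, 2 of them with groups that did not overlap. The median was -0.53, which lies between the predicted ranges and cannot tell. Of 10000 random lists of the same size and level, 1 was as low, and 95% lay between -0.14 and 0.16. These lists drew each gene independently and ignored that genes may vary together between libraries, so this share is not a p-value for the groups. Over libraries, the mean level of the second list differed by -0.73 on the log2 CPM scale (exact permutation p = 0.1, the smallest possible).

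The 4 Y-linked genes kept their proportions between MIRI 1 and MIRI 3, with ratios of 4.09 to 5.86 that differed by at most 1.43-fold. The ratios of MIRI 1 to MIRI 2 ran from 9.65 for Eif2s3y to 14.7 for Ddx3y, which had the lowest ratio to MIRI 3. Ratios this close fit different shares of male cells or animals in the libraries, but genes that respond together could also keep their proportions. A response of the same cells to MIRI stays open: the lowest MIRI library was at least 2.48-fold above the highest control in each gene, but the genes were chosen for groups that do not overlap, so this is no test of it. Sex was not given in the labels, and Xist had no row by position, so the sex of the samples could not be read from a second gene.

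A grouping of 3 against 3 has 10 splits, too few for a share under 0.05. The real split gave 0 genes and 0 lists with the deposited names and 0 genes by position, which all 10 splits reach by construction, so these counts say nothing on chance. The most in another split were 9 genes and 1 list with the deposited names, and 1 gene by position. By position the real split gave 3 lists, reached by 4 splits, with at most 4 in another. The endothelial list had the largest absolute median of log2 differences in the real split (3.73, 1 of 10 splits), with 2.34 as the highest other.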
